A study of Rattus norvegicus with 16 samples.

How the data were processed

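The spot intensities were deposited as Agilent Feature Extraction 10.7.3.1 output with no normalization between arrays, per the file headers. The processed intensity of a spot is its signal after subtraction of background and multiplicative detrending, floored above 0, and the median intensities of the spot and of its local background are raw pixel values, per the file headers. The 0 or 1 marks for a spot well above background, not uniform, far from its replicate spots or saturated were also set by Feature Extraction, per the file headers. Total RNA was labelled with Cy3 by the One Color Low Input Quick Amp protocol, per the labels. The authors also deposited a table of log2 values for the 58717 spots that are not controls; how those log2 values were normalized is not given in the sources used here. In that table the column medians lay between 7.33 and 7.36, and each of the 16 columns correlated best, across spots, with the log2 median intensity of its own array (r of 0.998 or more). That table was used only as an alternative.

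From the processed intensities, log2 values were computed and each array's 75th percentile over the spots that are not controls was subtracted. Spots marked as not uniform or as far from their replicates were left out and the replicate spots of a probe were averaged. Of 62976 spots, 4259 were controls; the rest came from 30367 probes, of which 13137 had 1 spot, 15840 had 2 and 1390 had 10. A further 23 probes had all spots left out on an array and were dropped. Probes well above background on at least 4 of the 8 arrays of a group were kept, which left 21808. HFT was compared with HF by limma (lmFit and eBayes, limma 3.58.1 in R 4.3.3) with no covariate, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. The files were read with the data.table package, version 1.17.8. Slide and position came from the file headers and were used for blocked fits.

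Probes were named through the RefSeq accessions that the array's annotation gives, matched without version to a table of rat genes (assembly GRCr8). This named 18005 of the 30367 probes (15168 genes) and left 12362 without a symbol. Of the kept probes 13739 had a symbol, for 11592 genes. The array design is labelled with build rn4, so no coordinates are given.

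The gene lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. Each list was tested with limma's camera with a preset correlation of 0.01, with 1 probe per gene, the one of highest mean signal, and with adjustment over the 29 lists. Camera with an estimated correlation and fry were run beside it. The limma adjusted p given for a list in an alternative fit is that of camera with the preset correlation. It is not a test of the list's mean over the animals. An exact permutation test of each list's mean per array, 4 marker lists of other tissues (epididymal epithelium, urothelium, liver, and sperm and spermatids) and 4 fits that leave out or adjust for arrays high on the epididymal or urothelial list were added after the data were seen. A high array is 1 whose list median lies over 3 log2 units above that of the median array. Genes were named by 3 parts of a rule. Of the genes past the adjusted threshold, the 12 of largest change in each direction would be named; where fewer passed, each direction was filled up to 8 with the genes of smallest unadjusted p and an absolute log2 difference of at least 0.5. In each list past camera, up to 4 members of smallest p in the list's direction were named, and in other lists up to 3 members past adjustment over the list alone. A panel of adipose genes was named whatever its values. 1 gene that the rule names is not reported here. Genes added after their values were seen are said to be so.

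The fit was tried on simulated data with 200 changed probes in 10 runs. With noise drawn from the real residuals it recovered 53.4% of probes changed 1.5-fold, 81.6% changed 2-fold and 92.6% changed 3-fold, and called a mean of 1.3 unchanged probes. A macrophage list shifted by 0.3 log2 units was called in 10 of 10 runs with the preset correlation and in 0 with an estimated correlation. With independent normal noise both called it in 10 of 10 runs and neither called a list without a shift. Normexp background correction, planned on the mean intensity of each spot, used the median intensity, since the files hold no mean intensity of the spots; its offset was 50.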

Results

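The series measured gene expression in epididymal white adipose tissue (EWAT), the visceral fat pad that lies along the epididymis, of male rat offspring killed at 30 days of age while feeding freely. Their dams were fed a high-fat diet in pregnancy and lactation and took either a low-fat condensed milk vehicle (HF) or, in that milk, 25 mg per kg body weight of a grape seed procyanidin extract (HFT). The pups ate their mothers' diet until they were killed. Each group held 8 animals, and each animal's total RNA was hybridised to its own 1-colour Agilent array, which gave 16 arrays of 62976 spots. The number of arrays, rather than a read depth, limits the precision. The 75th percentile of the signal ran from 753 (HF 10) to 1366 (HFT 28), no spot was saturated, and 68.3% to 73.4% of the probes lay well above background on an array. Animals are named by their group and the number in their label. The labels do not say which animals shared a dam, so the p-values treat littermates, if any, as independent.

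The 16 arrays filled 4 slides. Every slide held 2 HF animals at positions 1 and 2 and 2 HFT animals at positions 3 and 4, so a slide effect can be taken out of the comparison, whereas position on the slide and group cannot be told apart. The first 4 principal components of the kept probes held 38.5%, 16.3%, 8.77% and 7.53% of the variance. None separated HF from HFT in a two-sided exact permutation test (p = 0.616, 0.651, 0.788 and 0.0985). Component 1 set HF 8, HFT 23 and HFT 28 apart from the other arrays, and component 2 set HF 9, HFT 22, HFT 24 and HF 35 apart. Marker lists of other tissues, written after the components were seen, marked most of these arrays. Genes of the epididymal duct epithelium stood 8.16, 7.66 and 8.66 log2 units above the median array on HF 8, HFT 23 and HFT 28, and 2.50 on HFT 27. On the other 12 arrays that score lay between -1.02 and 0.64. Lcn5, a lipocalin of the epididymis, read 4.12, 3.42 and 4.12 on HF 8, HFT 23 and HFT 28, and -6.23 to -2.71 elsewhere. Genes of the urothelium, the lining of bladder and ureter, stood 5.09, 4.73 and 3.29 units high on HF 35, HFT 24 and HFT 22. Upk3a, a uroplakin of that lining, read 4.69, 4.69 and 2.95 there, and its highest value elsewhere was -5.98. Hepatocyte genes stood 3.96 and 3.41 units high on HF 10 and HFT 36, and sperm and spermatid genes 3.27 on HFT 28. Only 7 of 16 liver genes and 2 of 8 sperm genes were above background on all arrays not high for them, so these sizes are uncertain. Of the animals high for epididymal genes, 1 was HF and 2 were HFT. The same numbers held for the urothelial genes.

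**Figure D1:**
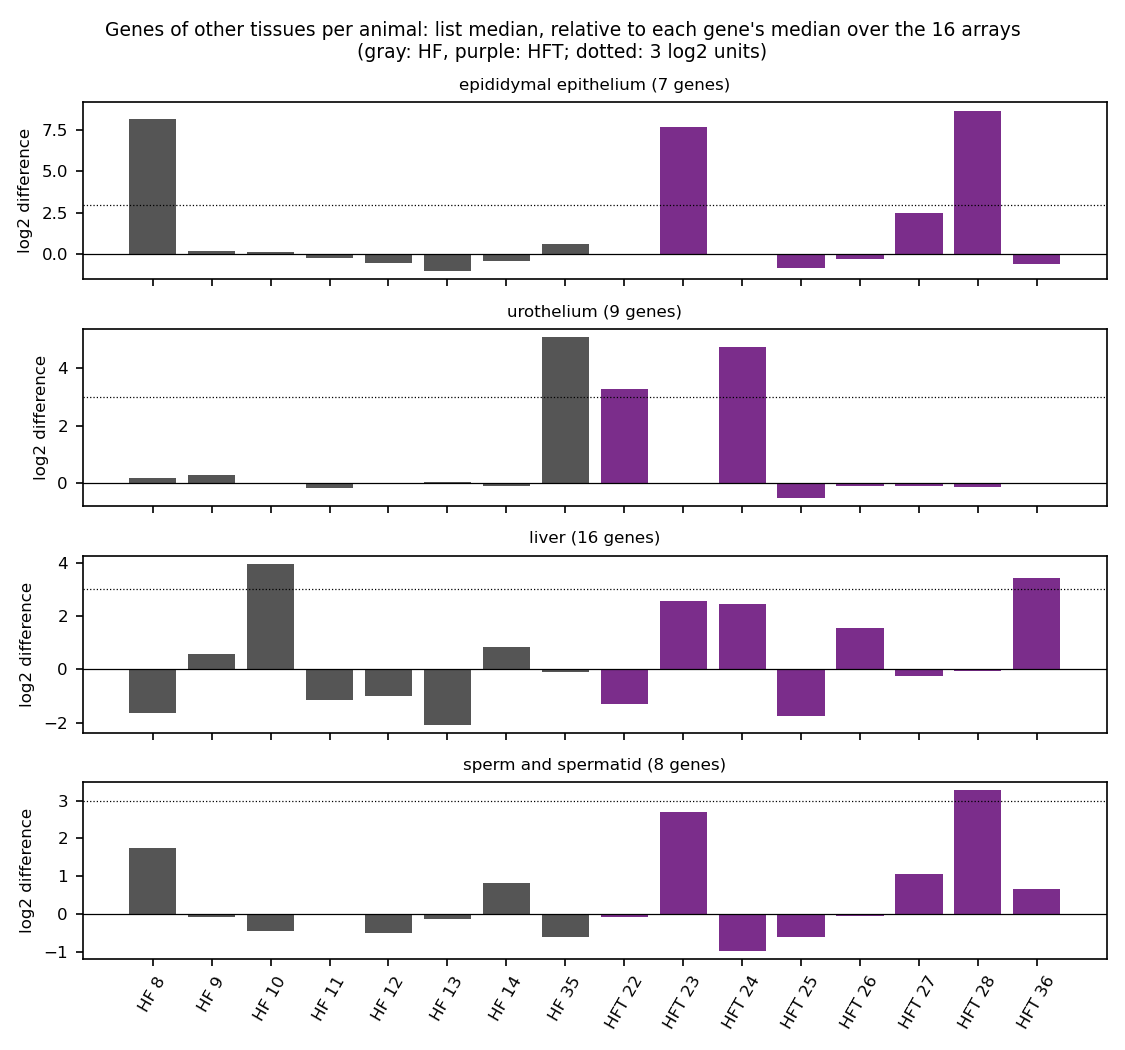
Score of 4 marker lists of other tissues on each of the 16 arrays, as the median over the list's genes of log2 signal relative to each gene's own median array, with 1 bar per animal and a dotted line at 3. HF 8, HFT 23 and HFT 28 stand at 8.16, 7.66 and 8.66 for epididymal epithelium, and HF 35, HFT 24 and HFT 22 at 5.09, 4.73 and 3.29 for urothelium.

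The single comparison of the design, HFT against HF, asks whether giving the extract to dams on a high-fat diet alters gene expression in the fat pad of their sons. No gene differed between HFT and HF beyond the spread between animals after adjustment for the number of probes. Leptin, adiponectin and the lipogenic enzymes Fasn and Scd differed by 0.33 log2 units or less. The clearest differences of gene lists lay in markers of other cells and in genes of acute signalling. Macrophage and blood cell markers averaged 0.28 and 0.30 log2 units higher in HFT, and immediate early genes and inflammatory cytokines averaged 0.44 and 0.29 units lower, as mean differences of -0.44 and -0.29. The median difference over the inflammatory genes was only -0.091. For each of these 4 lists the 95% interval over the 16 animals left out 0, yet none passed once the correlation between its genes was estimated. All differences are HFT minus HF on the log2 scale, and levels are log2 signal relative to the array's own 75th percentile, given as mean ± SD of 8 animals a group.

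Of 21808 probes tested with limma, 0 were higher and 0 lower in HFT at an adjusted p under 0.05, and the smallest adjusted p was 0.999994. At an unadjusted p under 0.05, 247 probes were higher and 268 lower, together 2.36% of those tested. With the slide as a block the count past adjustment was again 0, with 736 probes at an unadjusted p under 0.05. The estimated share of probes with no difference was 1, the median standard error of a difference 0.13, and 132 probes had a mean difference of 1 log2 unit or more in size.

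Among 29 gene lists fixed before the data were examined, 12 passed limma's camera test with its preset correlation of 0.01 between genes, 5 higher and 7 lower in HFT, and the same number passed with the slide as a block. With the correlation estimated from these arrays 0 passed, the smallest adjusted p being 0.140. Fry, which asks whether a list's genes move on balance in 1 direction, called 0 lists, with a smallest adjusted p of 0.298, and its mixed test, which asks for change in either direction, also called 0. The two-sided exact permutation test of each list's mean, over 12870 assignments of the animals, called 0, with a smallest adjusted p of 0.311. In data simulated from these arrays' own residuals with 200 probes changed and no list shifted, camera with the preset correlation called a mean of 9 of the 29 lists, and with the estimated correlation 0. A list shifted by 0.3 log2 units in such data passed in 10 of 10 runs with the preset correlation and in 0 with the estimated one, so its 0 lists here do not show that no list differed.

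**Figure D2:**
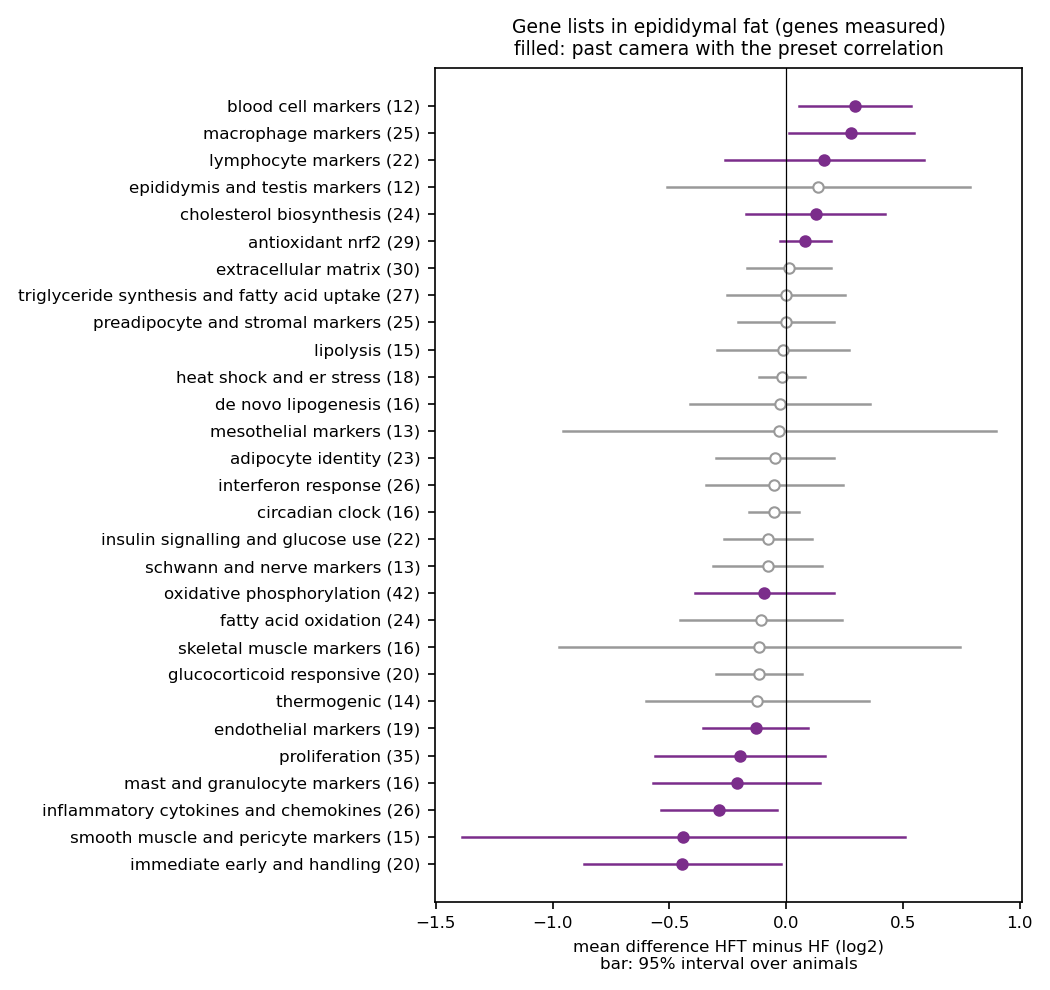
Mean HFT minus HF difference of each of the 29 gene lists in log2 units, with the 95% interval over the 16 animals; filled points mark the 12 lists past camera with the preset correlation. Macrophage markers stand at 0.28 and immediate early genes at -0.44, and no list passed with an estimated correlation.

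All 25 measured macrophage markers lay above 0, 8 of them at an unadjusted p under 0.05. Trem2, a lipid-sensing receptor of macrophages, differed by 0.85 (SE 0.34), from -1.77 ± 0.76 in HF to -0.92 ± 0.70 in HFT. Cd68, a lysosomal glycoprotein, differed by 0.35 (SE 0.13) and was above the HF mean in 8 of 8 HFT animals. Fcgr1a, the high-affinity receptor for IgG, differed by 0.28 (SE 0.12), Lyz2, a lysozyme, by 0.45 (SE 0.20), and Adgre1, which encodes F4/80, by 0.31 (SE 0.23). The list's mean difference was 0.28 (95% interval 0.013 to 0.55; camera adjusted p = 1.03e-16, and adjusted p = 0.140 with an estimated correlation). Within the 4 slides it was 0.20, 0.57, -0.16 and 0.51. The exact permutation p was 0.0429 before adjustment over the lists and 0.311 after it. Of 22 lymphocyte markers 18 lay above 0, with a mean difference of 0.16 (-0.26 to 0.59; camera adjusted p = 0.0255, and adjusted p = 0.544 with an estimated correlation). The T cell receptor complex gene Cd3g differed by 0.63 (SE 0.42), the coreceptor Cd4 by 0.29 (SE 0.17), the chemokine Ccl5 by 0.48 (SE 0.49) and Cd8b by 0.21 (SE 0.14). The call on lymphocyte markers ended with normexp background correction, where the mean difference was 0.0019 (limma adjusted p = 0.516), and without the arrays high for epididymal genes (0.10, limma adjusted p = 0.194).

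Of 12 blood cell markers 10 lay above 0. Ahsp, the chaperone of alpha-globin, differed by 0.66 (SE 0.17), was above the HF mean in 8 of 8 HFT animals, and read 0.76 higher on its other probe. Epb42, a protein of the red cell membrane, was not well above background on any HF array and was so on 7 HFT arrays. Its mean signals were -7.00 in HF and -6.13 in HFT. With each HF value set no lower than the lowest signal well above background on its array, it was 1.77-fold higher in HFT. That lowest signal can be of any probe and is not a detection limit for Epb42, so 1.77 is not a lower bound. Under normexp correction the difference of Epb42 was near 0, at -0.024. Pf4, platelet factor 4, differed by 0.30 (SE 0.11), and Alas2, the erythroid enzyme of heme synthesis, by 0.35 (SE 0.19). Adjusted over the list alone, Ahsp, Epb42 and Pf4 passed, with a smallest adjusted p of 0.0156 in limma; over all probes tested 0 did. The abundant haemoglobin genes Hba-a1, Hbb and Hbb-b1, named after their values were seen, differed by 0.015 (SE 0.10), 0.23 (SE 0.13) and 0.29 (SE 0.15). The list's mean difference was 0.30 (0.055 to 0.54; camera adjusted p = 2.39e-08, and adjusted p = 0.140 with an estimated correlation), and it was 0.57, 0.10, 0.057 and 0.45 within the slides. The exact permutation p was 0.0228, and 0.311 adjusted over the lists. With normexp correction the list's mean difference was 0.14.

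Cxcl1, a chemokine that draws neutrophils, had the steepest difference among the inflammatory genes, from -1.69 ± 1.57 in HF to -3.75 ± 0.77 in HFT. That is 4.15-fold lower in HFT (difference -2.05, SE 0.58, 95% interval -3.28 to -0.82), and all 8 HFT animals lay below the HF mean. Within the slides Cxcl1 differed by -3.55, -0.64, -2.81 and -1.22. The related chemokine Cxcl2 differed by -1.59 (SE 0.65) and Socs3, an inhibitor of cytokine signalling, by -0.54 (SE 0.16). Il10, an anti-inflammatory cytokine, read lower in HFT but was well above background on only 7 HF and 3 HFT arrays. Ccl2 differed by -0.39 (SE 0.30) and Tnf by -0.22 (SE 0.17), and the probe for Il6 was not well above background on any array. Of 26 inflammatory cytokines and chemokines 18 lay below 0 and 8 above. Their median difference was -0.091, nearer 0 than the mean given below, which Cxcl1 and Cxcl2 pulled down. Adjusted over the list alone, Cxcl1 and Socs3 passed, with a smallest adjusted p of 0.0478 in limma; over all probes tested 0 did. The list's mean difference was -0.29 (-0.54 to -0.040; camera adjusted p = 0.00167, and adjusted p = 0.209 with an estimated correlation), and it was lower in HFT on each of the 4 slides (-0.53, -0.081, -0.29 and -0.26). Its exact permutation p was 0.0298, and 0.311 adjusted over the lists. With probes well above background on all 16 arrays the mean difference was -0.19.

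Immediate early genes, which respond to stimuli and to tissue handling within minutes, lay lower in HFT for 18 of 20 members, 6 of them at an unadjusted p under 0.05. The transcription factor genes Junb and Atf3 differed by -0.90 (SE 0.35) and -0.77 (SE 0.34), and Zfp36, which encodes an RNA-binding protein that destabilises cytokine mRNA, by -0.63 (SE 0.27). Socs3 is also on this list. The mean difference was -0.44 (-0.87 to -0.021; camera adjusted p = 2.39e-08, and adjusted p = 0.208 with an estimated correlation). Within the slides it was -0.78, 0.28, -0.77 and -0.51, so slide 2 went the other way. The exact permutation p was 0.0413, and 0.311 adjusted over the lists.

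**Figure D3:**
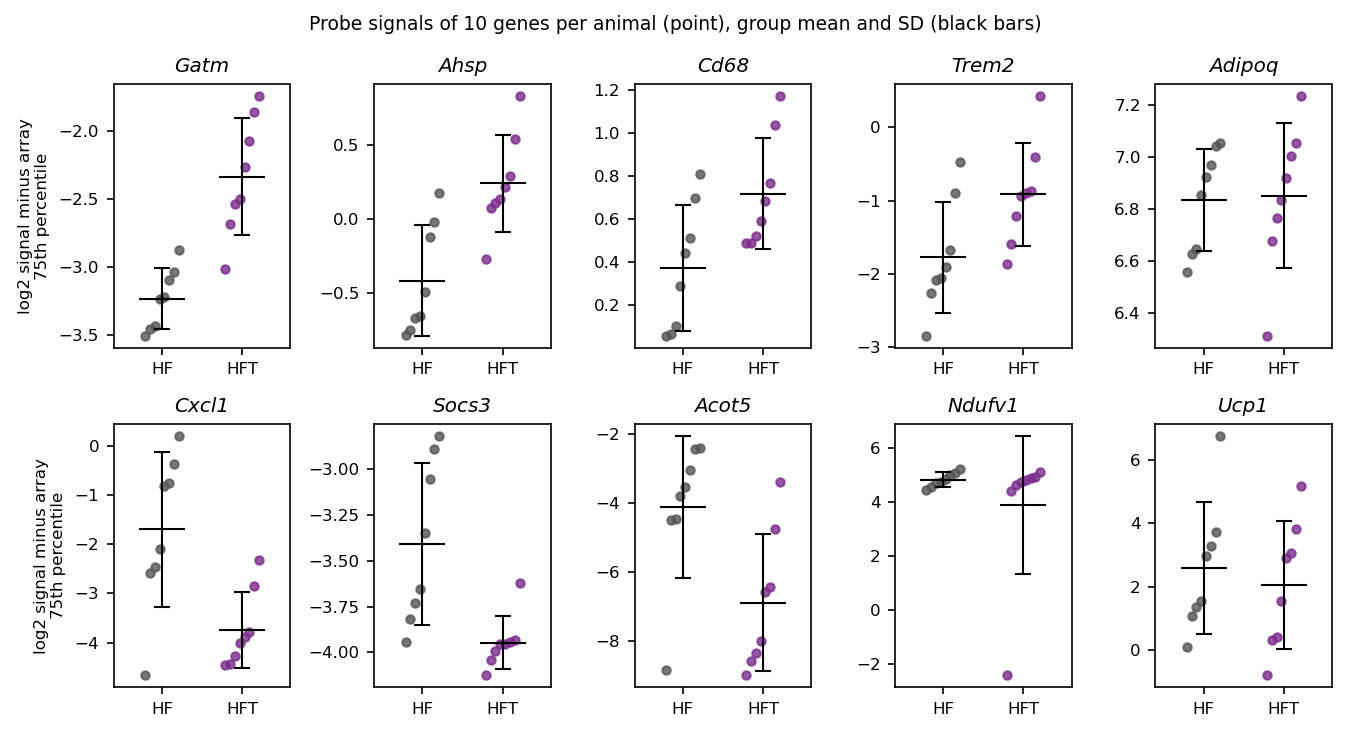
Log2 signal relative to the array's 75th percentile of 10 genes, with 1 point per animal and the mean and SD of each group of 8. Cxcl1 averages -1.69 in HF and -3.75 in HFT, Gatm -3.24 and -2.33, and Adipoq 6.83 and 6.85.

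Vascular, contractile and dividing cell markers lay lower in HFT, with wide intervals. Of 19 endothelial markers 18 lay below 0, with a mean difference of -0.13 (-0.36 to 0.093; camera adjusted p = 0.000427, and adjusted p = 0.544 with an estimated correlation). Plvap, a protein of endothelial fenestrae, differed by -0.23 (SE 0.11), the receptor gene Tie1 by -0.26 (SE 0.15), the cadherin gene Cdh5 by -0.36 (SE 0.22) and the TGF-beta coreceptor gene Eng by -0.23 (SE 0.14). Within the slides this list differed by 0.15, -0.37, -0.44 and 0.13. Without the 6 arrays high for epididymal or urothelial genes the call ended (mean difference -0.057, limma adjusted p = 0.0948), and without HFT 28 the mean difference was -0.069. It was -0.079 without the arrays high for epididymal genes and -0.085 with both tissue scores as covariates. Of 15 smooth muscle and pericyte markers 14 lay below 0, with a mean of -0.44 (-1.39 to 0.51; camera adjusted p = 0.00836, and adjusted p = 0.544 with an estimated correlation). This difference rested on HF 9, where the actin-binding protein gene Tagln read 5.56 against at most 2.66 in the other HF animals. Other genes, named after their values were seen, were high on that array too. The epithelial adhesion gene Epcam read -1.02 on HF 9 against -8.91 to -8.31 on 8 arrays, the keratin gene Krt15 read 0.43, and Ces5a and Wfdc10a read 3.68 and 4.08, their highest values on any array. Epcam read higher still, at -0.85 to 1.46, on the arrays high for epididymal or urothelial genes. Without HF 9 the mean was -0.073 (limma adjusted p = 0.383), and with normexp correction it was -0.40 (adjusted p = 0.171). With array weights the mean was -0.27, and without the arrays high for either tissue -0.67. Lmod1, Smtn, Tagln and Myl9, all genes of the contractile apparatus, differed by -0.86 (SE 0.44), -0.45 (SE 0.28), -0.63 (SE 0.50) and -0.53 (SE 0.43). The slides gave -1.33, 0.17, -0.073 and -0.53.

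Of 35 proliferation genes 34 lay below 0, with a mean difference of -0.20 (-0.56 to 0.16; camera adjusted p = 6.23e-07, and adjusted p = 0.544 with an estimated correlation). It was -0.22, -0.31, -0.039 and -0.22 within the slides. The mitotic genes Cdca8, Birc5, Bub1 and Racgap1 differed by -0.27 (SE 0.16), -0.37 (SE 0.22), -0.23 (SE 0.16) and -0.28 (SE 0.20). Without the arrays high for urothelial genes the call ended, at a mean of -0.027 (limma adjusted p = 0.743), and without those high for either tissue the mean was 0.014 (adjusted p = 0.819). HFT 24, 1 of the urothelial arrays, moved the mean to -0.098 when left out alone, and array weights moved it to -0.12. Of 16 mast cell and granulocyte markers 15 lay below 0, with a mean of -0.21 (-0.57 to 0.15; camera adjusted p = 0.00911, and adjusted p = 0.459 with an estimated correlation), and 0.038, 0.18, -0.53 and -0.54 within the slides. S100a8 and S100a9, which encode the calprotectin subunits of neutrophils, differed by -0.50 (SE 0.28) and -0.51 (SE 0.27) and were lower on all 4 slides. Without the arrays high for either tissue S100a8 and S100a9 differed by -0.016 and -0.039. The mast cell receptor gene Kit differed by -0.13 (SE 0.094) and the cathelicidin gene Camp by -0.15 (SE 0.12). Camp turned sign, to at most 0.073, without the arrays high for urothelial genes and without those high for either tissue. Leaving out HF 8 (mean -0.19, limma adjusted p = 0.0780), HF 14 (-0.16, 0.0753) or HFT 36 (-0.16, 0.0568) ended that call, as did dropping the filter on dim probes (mean -0.12, adjusted p = 0.0985) and leaving out the arrays high for epididymal genes (-0.15, 0.0934). Without the arrays high for urothelial genes the mean was -0.36, and without those high for either tissue -0.35.

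Metabolic lists differed by less. Of 24 cholesterol synthesis genes 21 lay above 0, with a mean difference of 0.13 (-0.17 to 0.42; camera adjusted p = 0.000676, and adjusted p = 0.571 with an estimated correlation) and slide values of -0.030, 0.29, 0.14 and 0.098. The enzyme genes Tm7sf2, Cyp51 and Fdps differed by 0.34 (SE 0.17), 0.22 (SE 0.20) and 0.28 (SE 0.26). Without HF 8 the call ended, at 0.055 (limma adjusted p = 0.152), and without HFT 26 the mean was 0.082. It was 0.082 with normexp correction too, 0.26 without the arrays high for either tissue and 0.21 with both tissue scores as covariates. Of 42 oxidative phosphorylation genes 40 lay below 0, by a mean of -0.094 (-0.39 to 0.20; camera adjusted p = 0.0161, and adjusted p = 0.834 with an estimated correlation), and 0.11, -0.10, -0.28 and -0.10 within the slides. The complex I genes Ndufa1 and Ndufs7 differed by -0.12 (SE 0.091) and -0.13 (SE 0.14), and Cox4i1, of complex IV, by -0.10 (SE 0.10). Ndufv1 averaged -0.94 (SE 0.85) because HFT 28 read -2.43, where the other HFT animals read 4.42 to 5.11. The oxidative phosphorylation call ended without HFT 23 (limma adjusted p = 0.331), HFT 26 (0.0746), HFT 28 (0.838), HF 10 (0.0556), HF 11 (0.255), HF 14 (0.0753) or HF 35 (0.825). Without HFT 28, HF 35 and HFT 23 in turn the mean was -0.0085, -0.040 and -0.060, without the other 4 it lay between -0.099 and -0.069, and without HF 8 it was -0.17. Normexp correction (-0.078, 0.964), quantile normalization (mean -0.063, adjusted p = 0.113) and the authors' deposited values (-0.059, 0.115) ended it too, as did leaving out the arrays high for epididymal (-0.030, 0.177) or urothelial genes (-0.067, 0.357). With both tissue scores as covariates the mean was -0.022. Without the 6 arrays high for either tissue the mean turned to 0.050.

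Genes of the antioxidant response under Nrf2 lay above 0 for 20 of 29 members, with a mean difference of 0.082 (-0.026 to 0.19; camera adjusted p = 0.0255, and adjusted p = 0.140 with an estimated correlation), and 0.10, 0.043, 0.20 and -0.017 within the slides. Thioredoxin reductase Txnrd1 differed by 0.17 (SE 0.081) and was above the HF mean in 8 of 8 HFT animals. Sulfiredoxin Srxn1 differed by 0.24 (SE 0.15), glutathione peroxidase Gpx1 by 0.11 (SE 0.075) and Ugdh, which makes UDP-glucuronate, by 0.15 (SE 0.11). That call ended without HF 8 (limma adjusted p = 0.0792), HF 9 (0.0636), HF 10 (0.0625), HFT 22 (0.0587), HFT 23 (0.10), HFT 24 (0.0910) or HFT 28 (0.0716). The mean in these fits lay between 0.061 (without HFT 23) and 0.096 (without HF 8), and it was larger than with all arrays without HF 8, HF 10 or HFT 22. The call also ended with array weights (0.072, 0.149), with the mean over a gene's probes (0.085, 0.0540), and without the arrays high for epididymal (mean 0.055, adjusted p = 0.298), urothelial (0.0995, 0.0796) or either set of genes (0.057, 0.819). The mean was thus larger, not smaller, without the urothelial arrays. It was 0.051 with normexp correction, 0.053 with probes well above background on all 16 arrays and 0.054 with both tissue scores as covariates. The lymphocyte call likewise ended without HF 9 (limma adjusted p = 0.307), HF 10 (0.106), HF 11 (0.0619), HF 14 (0.0739), HFT 23 (0.132), HFT 27 (0.0773), HFT 28 (0.434) or HFT 36 (0.0509), and with quantile normalization (0.14, 0.0870). Apart from HFT 28 the mean in these leave-one-out fits lay between 0.12 and 0.17. Without HFT 28 and without HF 8 the lymphocyte mean was 0.057 and 0.28. It was 0.11 with the authors' deposited values, 0.30 without the arrays high for urothelial genes and 0.055 with both tissue scores as covariates.

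Of the genes with an absolute difference of at least 0.5, the 8 of smallest p in each direction are named, although none passed adjustment. Gatm (probe A_42_P623688), the rate-limiting enzyme of creatine synthesis, differed most clearly. It read -3.24 ± 0.22 in HF and -2.33 ± 0.43 in HFT, 1.87-fold higher (difference 0.90, SE 0.17, 95% interval 0.55 to 1.25). All 8 HFT animals lay above the HF mean, the slides gave 0.18, 1.36, 1.19 and 0.88, and the gene's other probe differed by 0.40. Card9, an adaptor of antifungal signalling in myeloid cells, differed by 0.57 (SE 0.14), Zc3h12d, a zinc finger gene, by 0.59 (SE 0.15) and Bloc1s6, a subunit of a complex for lysosome-related organelles, by 0.51 (SE 0.14). Over the alternative fits the difference of Zc3h12d ranged from 0.22 to 0.86. Ahsp is also among these 8. Nme8, Lhfpl5 and Tceanc read higher in HFT but were well above background on at most 2 HF arrays, so no size is given. Under normexp correction their differences lay just below 0, between -0.090 and -0.00047.

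Acot5 (probe A_64_P103936), an acyl-CoA thioesterase, had the widest difference of the named genes, at -4.12 ± 2.06 in HF and -6.88 ± 2.0 in HFT. The mean signals differed by -2.77 (SE 0.95), with single animals anywhere between -9.00 and -2.41 and the probe well above background on 7 HF and 4 HFT arrays. With the authors' deposited values the difference was -1.55, and with normexp correction -0.9997. Without the arrays high for epididymal genes, a setting chosen after the data were seen, Acot5 passed with a limma adjusted p of 0.0131. The 3 arrays left out were the exceptions to the difference: HF 8 read -8.83, the lowest HF value, and HFT 23 and HFT 28 read -3.38 and -4.74, the highest HFT values. Of the 6 HFT arrays that remained, at -9.00 to -6.43, only 2 were well above background. With their values set no lower than the lowest signal well above background on the array, Acot5 was 14.4-fold lower in HFT among the 13 animals left. That lowest signal can be of any probe and is not a detection limit for Acot5, so 14.4 is not a lower bound. Without the arrays high for either tissue the limma adjusted p was 0.130. Sytl5, which encodes a vesicle transport protein, differed by -0.91 (SE 0.28) and Marchf9, a membrane ubiquitin ligase gene, by -0.52 (SE 0.15). Mill1, Or52ae9 and Lrrc3 read lower in HFT but were well above background on 4 HF arrays and 1 HFT array each, so no size is given. Cxcl1 and Socs3 complete this direction.

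Genes of the fat cell itself differed by less than the spread between animals. Adiponectin (Adipoq) read 6.83 ± 0.20 in HF and 6.85 ± 0.28 in HFT, a difference of 0.016 with a 95% interval of -0.24 to 0.27. Leptin (Lep) differed by 0.33 (-0.15 to 0.80). The stearoyl-CoA desaturase gene Scd differed by -0.051 (-0.26 to 0.16), and fatty acid synthase Fasn by -0.085 (-0.56 to 0.39). The adipogenic factors Pparg and Cebpa differed by -0.15 (SE 0.15) and -0.11 (SE 0.20), the lipid carrier Fabp4 by 0.10 (SE 0.16) and lipoprotein lipase Lpl by -0.044 (SE 0.16). The lipases Pnpla2 and Lipe differed by -0.27 (SE 0.18) and -0.094 (SE 0.17), the glucose transporter Slc2a4 by -0.24 (SE 0.20), Pck1 of glyceroneogenesis by -0.060 (SE 0.38) and the preadipocyte factor Dlk1 by -0.26 (SE 0.44). Ucp1, the uncoupling protein of thermogenic fat cells, differed by -0.54 (SE 0.96) and ranged from -0.80 to 6.75 between animals. Mki67 had no matched probe. The differences of Adipoq, Cebpa, Fasn, Scd, Lpl, Lipe, Pck1, Ucp1 and Dlk1 changed sign in at least 1 alternative fit. Of these, only Scd and Lpl did so under another processing of the values, the authors' deposited ones. The others did so only in fits that left out arrays or took both tissue scores as covariates.

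Ucp1 varied far more between animals than between groups, and of the 13 other measured genes of the thermogenic list Cox8b and Cidea varied most closely with it. All 13 were set against Ucp1, but only after the values of Ucp1, Cox8b and Cidea had been seen, so the p-values of that pair are not independent evidence. Cox8b, a subunit of cytochrome c oxidase found in brown fat and muscle, ran from -1.27 (HFT 26) to 4.66 (HF 35), a 60.7-fold range, and Cidea, a lipid droplet protein of thermogenic fat, from 3.40 to 5.65. The highest values of Ucp1 and Cox8b were those of HF 35 (6.75 and 4.66) and HFT 22 (5.18 and 3.78), both among the 3 arrays high for urothelial genes. HFT 24, the third of these, read 3.06 and 2.44. Across the 16 animals Ucp1 and Cox8b gave Pearson's r = 0.986 and Spearman's rho = 0.982 (two-sided permutation p = 1e-05 for each, the smallest that the permutations can give). Ucp1 and Cidea gave r = 0.929 (permutation p = 1e-05) and rho = 0.915 (permutation p = 2e-05). Adjusted over the 14 relations computed, the permutation p was 7e-05 for r and 0.00014 for rho in each pair. Without the 2 animals farthest from the median of Ucp1, r was 0.981 with Cox8b and 0.915 with Cidea, and with slide means taken out it was 0.976 and 0.899. Without the 3 arrays high for urothelial genes it was 0.981 and 0.866. Otop1, a proton channel gene, gave r = 0.756 (permutation p = 7e-04, adjusted 0.00245) and rho = 0.862 (permutation p = 7e-05, adjusted 0.000327), with r = 0.791 without the 2 animals, 0.684 with slide means taken out and 0.801 without the urothelial arrays. Dio2, the deiodinase that activates thyroid hormone, and Pank1, a pantothenate kinase gene, passed by r (0.594 and 0.5999; adjusted permutation p = 0.0338 for each) and not by rho (0.518 and 0.441; 0.0852 and 0.153). Without the urothelial arrays their r was 0.16 and -0.042, so those relations rested on these arrays. The other 8 genes gave r between -0.467 and 0.509 and did not pass by r; Ucp3 among them passed by rho (0.594, adjusted permutation p = 0.0482).

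**Figure D4:**
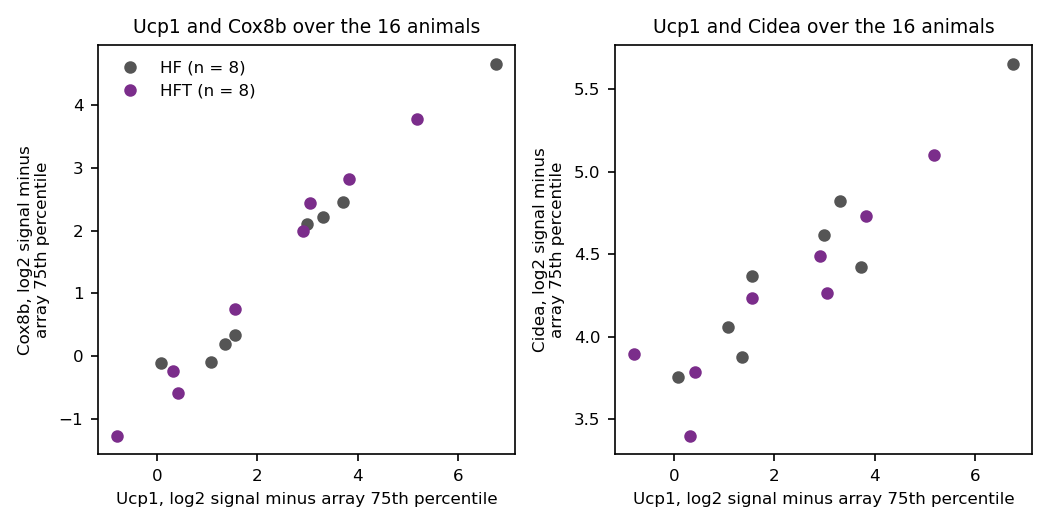
Log2 signal of Ucp1 against that of Cox8b and of Cidea, each relative to the array's 75th percentile, with 1 point per animal in the colour of its group. Ucp1 spans -0.80 to 6.75, r is 0.986 with Cox8b and 0.929 with Cidea, and both groups cover most of the range.

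The other 17 lists did not pass camera with either correlation, although 7 of them passed in some alternative fits with the preset one. Adipocyte identity genes (9 of 23 above 0) averaged -0.049 (-0.30 to 0.20), de novo lipogenesis -0.026 (-0.41 to 0.36), triglyceride synthesis and fatty acid uptake -0.00013 (-0.25 to 0.25), lipolysis -0.013 (-0.30 to 0.27), and insulin signalling and glucose use -0.077 (-0.26 to 0.11). Of 24 fatty acid oxidation genes 21 lay below 0, with a mean of -0.11 (-0.45 to 0.24; limma camera adjusted p = 0.112). That list passed in 7 alternative fits: with array weights (-0.11, limma adjusted p = 0.0309) and without HF 8, HF 9, HF 13, HFT 22, HFT 25 or HFT 36, with means of -0.17 to -0.12 and a smallest adjusted p of 0.00171 without HFT 22. Thermogenic genes averaged -0.12 (-0.60 to 0.36), interferon response genes -0.050 (-0.34 to 0.24), and extracellular matrix genes 0.014 (-0.17 to 0.19). Preadipocyte and stromal markers averaged -0.0016 (-0.21 to 0.20), Schwann cell and nerve markers -0.079 (-0.31 to 0.15), and mesothelial markers -0.029 (-0.96 to 0.90). Epididymis and testis markers averaged 0.14 (-0.51 to 0.79) and skeletal muscle markers -0.11 (-0.97 to 0.74). Heat shock and endoplasmic reticulum stress genes averaged -0.017 (-0.12 to 0.082), circadian clock genes -0.052 (-0.16 to 0.055) and glucocorticoid-responsive genes -0.12 (-0.30 to 0.068). Mesothelial markers passed without the arrays high for epididymal genes (-0.22, limma adjusted p = 0.0459) and without those high for either tissue (-0.69, 9.69e-07), and interferon response genes without those high for epididymal genes (-0.15, 0.00425). The urothelial arrays HF 35, HFT 24 and HFT 22 also had the highest mesothelial means, 1.24, 1.22 and 1.19 above the average array. Of the 9 urothelial genes measured, 3 were on a list fixed before. The mesothelial value without the arrays high for either tissue is therefore not independent of how those arrays were chosen. Glucocorticoid-responsive genes passed with array weights (limma adjusted p = 0.0309) and without HF 9 (0.0344) or HF 35 (0.0426). Insulin signalling genes passed with array weights (limma adjusted p = 0.0360) and without HF 8 (0.0303), triglyceride synthesis genes with both tissue scores as covariates (0.076, 0.0222), and extracellular matrix genes with normexp correction (0.018, 0.0115). Camera's direction, relative to all other genes, differed from the sign of the mean or of the median in 6 of these lists. They were triglyceride synthesis, lipolysis, preadipocyte, skeletal muscle and heat shock genes, where camera pointed up, and epididymis and testis genes, where it pointed down.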

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

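The 3 tests of the epididymal pattern below were chosen after the result was seen. Of 212 groups of 8 animals, each a named gene or a list in HF or HFT, 21 (9.91%) had an animal whose gap to its nearest neighbour took an unusually large share of the group's range. Chance gives about 1 in 20. The share is given after each animal's value and that of its neighbour.

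HFT 28 had 7 of them: Ndufv1 (-2.43, nearest 4.42; share 0.909), Lyz2 (4.09, nearest 3.39; 0.538), S100a9 (-4.84, nearest -3.82; 0.608), S100a8 (-5.86, nearest -4.71; 0.645), Lipe (0.054, nearest 0.65; 0.544), and the means of adipocyte identity genes (2.55, nearest 2.92; 0.527) and of insulin signalling genes (-0.52, nearest -0.16; 0.635). HF 8 had 4: Acot5 (-8.83, nearest -4.49, share 0.676), Cd8b (-7.19, nearest -6.34, 0.728), Ccl5 (0.46, nearest -1.23, 0.572) and the mean of epididymis and testis markers (-2.88, nearest -3.87, 0.591). HF 9 had 4, all contractile: Smtn (4.19, nearest 2.73, share 0.584), Tagln (5.56, nearest 2.66, 0.674), Myl9 (6.11, nearest 3.37, 0.703) and the mean of smooth muscle markers (3.21, nearest 1.30, 0.543). HF 35 stood high for Cd3g (-2.82, nearest -4.64, share 0.624) and for the mean of thermogenic genes (-0.0023, nearest -0.77, 0.54). Single cases were Il10 low in HF 10 (-7.02, nearest -6.16, share 0.555), Tnf high in HF 11 (-1.38, nearest -2.01, 0.548), clock genes high in HFT 24 (-1.57, nearest -1.74, 0.541) and Socs3 high in HFT 25 (-3.62, nearest -3.93, 0.613).

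HFT 28, HF 8 and HFT 23 are the arrays high for genes of the epididymal epithelium. HFT 23 had none of these values, and HF 9, with as many as HF 8, was not high by that score (0.22), which is a median over the list. Genes outside the list, picked after their values were seen, did stand out on HF 9. Ces5a (3.68) and Wfdc10a (4.08) read higher there than on any other array. On HF 8, HFT 23 and HFT 28 Ces5a read 1.89, 0.61 and 2.08, and Wfdc10a 1.90, 0.22 and 1.76. Part of the list was raised on HF 9 too. Pax8 and Lrp2 read -3.09 and -2.35, against at most -4.17 and -4.00 on the other arrays not high. Cdh16 read -2.41, below HFT 27 (-1.65) and above the rest of these. Lcn5, Lcn10, Ptgds and Foxj1 lay within the range of those arrays. Epcam read -1.02 on HF 9 against -8.91 to -8.31 on 8 arrays. The arrays high for epididymal or urothelial genes read higher still for Epcam, at -0.85 to 1.46. On the high arrays the prostaglandin D synthase gene Ptgds read 5.14, 4.65 and 4.27. A slide or hybridisation batch is argued against, since every slide with a high array also held an array that was not high, with lowest scores of at most -0.061. A candidate explanation is epididymal tissue carried along with the fat pad: after each array's mean was taken out, the list's genes had a median range of 0.33 log2 units over the high arrays, as 1 tissue in differing amounts would give. Of the 7 genes measured, 4 were above background on all 13 other arrays and 1 was on a list fixed before, and the labels name no step that would remove such tissue. Whether the maternal treatment alters how often arrays are high stays open, with 1 HF and 2 HFT arrays high (two-sided Fisher's exact p = 1, 95% interval of the odds ratio 0.0927 to 157).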

How the results depend on the processing

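All alternatives were chosen before the data were examined except the 4 fits on arrays high for other tissues' genes and the exact test of lists. Scan date as a block was not run, since each slide had a single scan. Counts past the adjusted threshold were 0 higher and 0 lower in 30 of the 31 alternative probe fits and at an adjusted p under 0.10. The exception was the fit without the arrays high for epididymal epithelium genes, with 1 probe lower (Acot5, limma adjusted p = 0.0131). Over the leave-one-out fits the smallest adjusted p was 0.136, of Gatm. At an unadjusted p under 0.05, 247 were higher and 268 lower, together 515. That total was 955 with normexp correction (122 higher and 833 lower), 262 with the mean over a gene's probes (fewer tests), 1206 without the arrays high for either tissue and 1040 with both scores as covariates, and 440 to 681 over the leave-one-out fits; apart from the fewer tests, the cause was not tested. Of the lists, 12 passed camera, 9 to 14 passed in the alternative fits, and 0 passed with camera with estimated correlation, with fry or with the exact permutation of the list mean. The estimated correlations of the 12 lists had a median of 0.356. Macrophage, blood cell, inflammatory and immediate early lists passed under every one of the 31 fits. Oxidative phosphorylation turned from -0.094 to 0.050 without the arrays high for either tissue (adjusted p = 0.202); the cause was not tested. With both scores as covariates the adjusted p was 0.762 for oxidative phosphorylation, 0.310 for lymphocyte markers and 0.189 for antioxidant genes. Of 957 alternative values of lists, 788 kept their side and direction, 73 lost the call, 17 gained one, 78 without a call turned direction and 1 reversed. Of 77 named genes, 59 kept their sign under every alternative and 18 did not. Among the single genes Nme8, Lhfpl5, Tceanc, Cd8b and Epb42 turned sign under normexp. Their differences there lay near 0, at -0.00047, -0.090, -0.0059, -0.092 and -0.024. Mill1, Or52ae9, Lrrc3 and Il10, dim on many arrays too, kept theirs, and dim signal as the cause was not tested.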

Other observations

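The tests given here were chosen after the results were seen, except the 2 on position and camera with an estimated correlation. Cxcl1 varied with the immediate early genes from animal to animal. Over the 16 animals the level of Cxcl1 and the mean of the immediate early list, which does not hold it, gave Pearson's r = 0.796 (two-sided permutation p = 0.00031) and Spearman's rho = 0.788 (permutation p = 0.00057), with permutation p of 0.00145 and 0.00199 after adjustment over the 14 relations computed. Without the 2 animals farthest from the median of Cxcl1, r was 0.687, with slide means taken out 0.809 and with group means taken out 0.708. It was 0.847 within HF and 0.282 within HFT, a difference that was not tested.

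Other genes sat at separate levels. Of 19574 probes above background on all arrays, 66 split the animals into a pair of levels at least 1 log2 unit apart, with a separation of at least 8 times the spread within a level. Of these, 51 set apart the arrays high for epididymal genes and 6 those high for urothelial genes. Among the 9 whose high arrays matched neither set exactly was Sgcb, a sarcoglycan. It read 0.032 in HF 11, -0.089 in HF 13 and 0.25 in HFT 27 and between -2.53 and -1.73 in the rest. Ngef read -0.87, -0.57, -1.73 and -0.93 in HF 8, HF 9, HFT 23 and HFT 28, and -3.74 or lower elsewhere. Its high arrays, like those of a probe without a symbol, were thus the arrays high for epididymal genes together with HF 9. Calcb, a calcitonin-related peptide, stood high in HFT 24 and HF 35, at -1.40 and -2.48. These are the arrays with the highest urothelial scores, and HFT 22, the third such array, read next highest at -4.04. HF 9, high for contractile genes, also had high Myh11 (6.22), Des (4.76) and Acta1 (3.67).

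The number of gene lists called is the first pattern weighed: of 100 splits of the animals into groups of 8, the real one included, 16 gave 12 lists or more, with 15 the highest of the others, so chance cannot be excluded. Unlike the real one, the other splits were not kept balanced over the slides. Of the 100 splits, 24 had all 3 arrays high for epididymal genes on one side. For 11 of the 12 lists the estimated correlation between genes lay above the preset of 0.01, with a median of 0.356 over the 12. With no list shifted, the preset called a mean of 9 lists in data simulated from the real residuals and 0 with independent noise. A preset correlation lower than theirs can thus give many calls without a shift. Whether it gave all 12 stays open. With an estimated correlation 0 of the 12 stayed past the threshold, but that test passed a list with a known shift in 0 of 10 simulated runs, so it cannot decide. Of the 12 lists, 6 passed in all 4 fits that leave out or adjust for the arrays high for epididymal or urothelial genes. For blood cell markers RNA of these epithelia as the whole source is argued against, as far as the scores capture it. Their 95% interval left out 0 with both scores as covariates (0.097 to 0.57) and without the arrays high for either (0.054 to 0.68). For macrophage, inflammatory and immediate early genes only the interval with covariates left out 0. Without those arrays these lists differed by 0.35, -0.31 and -0.41, with intervals that held 0, so this source stays open for them. HF 9, where Ces5a and Wfdc10a read highest, stayed in all 4 fits with an epididymal score of 0.22, so tissue that the scores miss was not tested. Cholesterol genes differed by 0.21 (-0.013 to 0.42) with covariates and by 0.26 (0.035 to 0.48) without the arrays high for either, against 0.13 with all arrays. As only the second interval left out 0, this source stays open for cholesterol. It also stays open for smooth muscle (-1.45 to 0.44 with covariates, -2.23 to 0.89 without those arrays), and for the 6 that lost the call. In those 6 the median share of the difference left with covariates was 0.652, and the shares ran from 0.232 to 1.12 over the lists. Position on the slide cannot be told apart from group: the step from position to position within a group, times 2, left out the group difference in 3 of the 12 lists and lay beyond 0 on its side in 0.

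The antioxidant list stood apart from the other called lists. Its estimated correlation was -0.0033, its camera p was 0.0106 with the preset and 0.0118 with the estimate, and it lost the call through adjustment over the lists (adjusted p = 0.140). Its call also ended without the urothelial arrays, where its mean was 0.0995 against 0.082 with all arrays. Without the arrays high for either tissue, which leaves 6 HF and 4 HFT animals, the 95% intervals of macrophage (-0.063 to 0.75), inflammatory (-0.70 to 0.078) and immediate early genes (-0.97 to 0.15) held 0.

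The lower level of Cxcl1 and the immediate early genes in HFT is the second pattern. For the list, RNA of epididymal and urothelial epithelium stays open. With both scores as covariates the list differed by -0.49 (95% interval -0.93 to -0.044), which leaves out 0. Without the arrays high for either tissue it differed by -0.41 (-0.97 to 0.15), which holds 0. Position on the slide stays open: the step within a group, times 2, was 0.13 (-0.91 to 1.17) for the list, too wide to decide. For Cxcl1 alone it was 1.46 (-1.56 to 4.48), which leaves out that gene's difference of -2.05, under the assumption of an even step along the slide. The order in which animals were killed and tissue taken is not given in the sources used here, so neither handling nor the maternal treatment was tested apart.

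For single probes, 70 of the 100 splits gave as many as the 515 of the real one at an unadjusted p under 0.05, with 4287 the highest of the others, so chance cannot be excluded there. The splits with 4287 probes and with the lowest share, 0.673, both had all 3 arrays high for epididymal genes on one side, where the real one has 2. The real split had 0 probes past the adjusted threshold and an estimated share of 1 with no difference. All 100 splits therefore had to give at least as many probes, and all 100 a share as low, so these comparisons say nothing about chance. Of the others, the highest number of probes was 385.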
